A study of Mus musculus with 4 samples.

How the data were processed

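Total RNA from RAW264.7 cells, a mouse macrophage-like cell line, was hybridised to 4 one-colour Affymetrix mouse arrays. Of these, 2 arrays carried RNA from cells infected with murine norovirus strain MNV-1 and 2 carried RNA from mock-infected cells. Per the labels' protocols, RNA was extracted on silica columns and biotin-labelled cRNA was prepared from 6 ug of total RNA. The table the authors deposited holds a probe set intensity for each array on a linear scale, and these values had been made with RMA (robust multi-array average, which corrects background, normalises between arrays and summarises the probes of a probe set), per the submitters' processing notes. The RMA version and settings are not given in the sources used here. RMA usually gives log2 values, but the deposited intensities were whole numbers from 3 to 16184, so they had been taken out of the log scale and rounded. Log2 was therefore taken before any test, with no pseudocount. Rounding leaves steps at the dim end, and 1.839% of the genes tested had no spread within either group.

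The table held 45101 probe sets. Of these, 64 were controls, 34945 had 1 gene symbol in the platform annotation used, 932 had several and 9160 had none there. The Entrez identifiers of 34741 probe sets with 1 symbol were found in the reference gene table, and 0 symbols needed an update. Each gene was represented by the probe set with the highest mean over the 4 arrays. Genes whose mean lay under the 25th percentile of all non-control probe sets, an intensity of 6.701, were left out, and 15663 genes were tested. No genome was used here, so no positions are printed. Probe sets whose names end in _s_at or _x_at can bind transcripts of related genes, and 9 of the 72 genes named by rule rest on such a probe set. Of the 5048 genes past the threshold, 2752 had over 1 probe set that passed the intensity filter, and in 712 of these such probe sets changed in both directions. Dimmer probe sets of a gene were not compared. Among the genes named in the text, other probe sets moved much less for Ifi209 (log2 change 3.41), Anln (-1.84), Uqcrb (-0.55), Cyp51 (-0.84), Rps9 (-0.21) and Fkbp4 (-0.35). The same held for Shmt2 (-0.92), Tigar (-0.29), Ctsa (-0.08), H2-D1 (0.63) and Stag1 (-0.14), beside those given with their gene. Other probe sets moved the other way for Rbl1 (0.73), Sel1l (0.16), Mcoln1 (0.44), Stag2 (0.13), Bcl2 (0.08) and Irf3 (0.05). The table has no detection calls. The 3 Trpn negative-control probe sets read between 4 and 6, and a gene with both arrays of a group at or under 6 was taken as not above background there. For such a gene the fold is given as a lower bound, the brighter group's geometric mean over 6. The list medians are the same with such genes at their bounds, which lie on the same side of the median as the fitted changes.

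Infected and mock arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, infected minus mock, all 4 arrays, no covariates). Genes with a Benjamini-Hochberg adjusted p under 0.05 over the genes tested were called. The prior had 1.537 degrees of freedom beside 2 residual ones. Changes are given as log2 differences with limma's standard error (SE), and every value rests on 2 infected and 2 mock arrays. The labels number the replicates but do not say that they came from separate cultures. The p-values then measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision.

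The test, the filters, 23 gene lists and the rule for naming genes were fixed before the data were examined. The lists were tested with camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 23 lists. Beside each called list stands the adjusted p from camera with an estimated correlation. None of the 15 called lists held with an estimated correlation (adjusted p from 0.306 to 0.581), and 3 lists, the interferon-stimulated, NF-kB target and immediate early genes, had an unadjusted p under 0.05 there. That test has 2 residual degrees of freedom here. The count of members passing was also taken with the gene test adjusted over the list alone. Of the 643 list entries, 49 were matched to no probe set with a single gene and were not analysed here. The rule named the 8 largest rises and 8 largest falls, the 3 members that moved furthest in the direction of each called list, the 1 member that moved furthest in each other list, and 11 genes chosen in advance. Of those 11 genes, 2 were not analysed here. Further genes are named where few members of a list moved or where a member stood out, and these were chosen after their values were seen.

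The scripts were tested on simulated arrays (15663 genes, infected minus mock), with the residual spreads of these genes shuffled between genes. Dim and bright genes thus drew from the same spreads before rounding, so the rates below may not hold at a given intensity. In the first simulation 200 genes with a mock mean above an intensity of 64 were changed. Of these, 0% were called at a log2 change of 0.5, 10% at 1, 30% at 2 and 40% at 3, and 0% of unchanged genes were called. With as many genes changed as were called here, 36.81% of changes up to a log2 size of 0.5 were called, 58.92% of those from 0.5 to 1, 83.45% of those from 1 to 2 and 96.97% of those above 2. In that simulation 2.544% of unchanged genes were called, and 6.81% of all calls were false. The list test called 1 of 1 shifted list and 0 of 20 unchanged lists. The simulated genes varied independently and these lists were drawn at random. The simulation therefore could not test whether the preset correlation of 0.01 is too low for the real lists.

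The alternatives tried were no filter, a filter at the median (intensity of 14.99), the mean of a gene's probe sets, all probe sets as features, median centring, quantile normalisation applied again, cyclic loess, a variance trend, a robust prior, array weights, the replicate number as a block, each array left out, fold limits of 1.5 and 2, an adjusted p under 0.1, limma's treat against a 1.2-fold change, and camera with an estimated correlation, camera on ranks and fry for the lists. A filter at an intensity of 64, the same filter with each array left out, and random draws within the rounding step (20 draws, up to 0.5 either way) were added after seeing the data.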

Results

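Gene expression was measured in RAW264.7 cells, a macrophage-like line from a mouse leukaemia virus-induced tumour, after infection with MNV-1, an RNA virus of the mouse that grows in macrophages. The question was how infection changes the transcripts of the host cell. Of the 4 arrays, 2 were from cells infected at a multiplicity of 1 and 2 from mock-infected cells. The labels disagree on the time. The treatment protocol gives 12 h, while the source names give 18 h and speak of transfection, so the hour at which the cells were collected is not settled. The arrays had median intensities of 15 and 16 (infected replicates 1 and 2) and 14 and 15 (mock replicates 1 and 2), close to the negative controls at 4 to 6. Across the genes tested, Pearson correlations of log2 values were 0.992 between the infected arrays, 0.994 between the mock arrays, and 0.889 to 0.910 between arrays of different groups.

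Signs of RNA quality moved with infection in part, and they stand beside every gene group described here. The difference between the 3' and 5' beta-actin controls was 0.21 and 0.29 log2 units in the infected arrays and 0.51 and 0.41 in the mock arrays. For the Gapdh controls it was -0.15 and -0.02 in infected and -0.14 and -0.13 in mock arrays. The 5' control for 18S ribosomal RNA read 550 and 388 in infected and 63 and 16 in mock arrays. The spiked poly-A controls of mock replicate 2 had a geometric mean of 113.8, against 293.1 in mock replicate 1 and 377.7 and 276.7 in infected replicates 1 and 2.

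Infected cells carried interferon and inflammatory transcripts at levels far above mock cells and had lower transcripts for cell division. Of 15663 genes tested, 2132 (13.6%) were higher and 2916 (18.6%) lower in infected cells. The excess of lower genes depended on scaling: 3082 were higher and 3094 lower under cyclic loess, and 1927 and 3797 with median centring. Median centring moved the median log2 change of the genes tested from 0.027 to -0.069. That shift rests on whole-number array medians of 14 to 16, where rounding steps are coarse. Rises reached further than falls: 425 genes rose and 433 fell at least 4-fold, but 119 rose and 7 fell at least 16-fold. The floor limits this contrast. A probe set at the array median, 14 to 16, could show a 16-fold rise but no such fall, as negative controls read 4 to 6. The largest fitted rise was in Ifit1bl1, a relative of the interferon-induced Ifit1, which read 6847 and 7226 in infected and 8 and 8 in mock arrays (log2 change 9.78, SE 0.083). Ifi209, of the interferon-induced p200 family, was at the negative controls in mock cells and was at least 603-fold higher in infected cells. Its rank against Ifit1bl1 is therefore not settled. Then came Ifit1 (9.14), Mx1 (9.12), Ifit3 (8.98), Gbp2b (8.79), Rsad2 (8.77) and Cmpk2 (8.63). This order holds for the brightest probe set of each gene, as other probe sets of Rsad2 and Cmpk2 rose by up to 9.24 and 9.41. Mock arrays read 8 and 5 for Mx1, 10 and 16 for Ifit1, 10 and 10 for Gbp2b and 13 and 12 for Cmpk2. These genes and Ifit1bl1 were not far above the negative controls there, so the size and rank of their rises are uncertain. The largest falls were in Esco2, a cohesin acetyltransferase (-4.96, SE 0.32), Aspm, a spindle protein (-4.62, SE 0.40), C130050O18Rik (-4.48), the cohesin regulator Cdca5 (-4.29), Anln (-4.25), Tk1 (-4.22), Ydjc (-4.02) and the mitotic kinase Pbk (-3.96, a probe set that can bind related transcripts). In infected arrays Esco2 read 7 and 4 and Aspm 9 and 7, near the negative controls, so the size and rank of their falls are uncertain. The adjusted p of these 16 genes lay between 0.0011 and 0.00857 (limma). In all 5048 called genes both infected arrays lay on one side of both mock arrays. The same held for 64.04% of the genes tested, where chance gives 33.3%. With infected replicate 1, infected replicate 2, mock replicate 1 or mock replicate 2 left out, limma called 0 genes higher and 0 lower, and 6080, 5196, 4879 and 5164 genes had an unadjusted p under 0.05. With genes under an intensity of 64 removed, a filter chosen after seeing the data, 3861, 3373, 3456 and 3545 genes were called without those arrays in turn, of which 1213, 1258, 1521 and 1444 were higher.

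**Figure D1:**
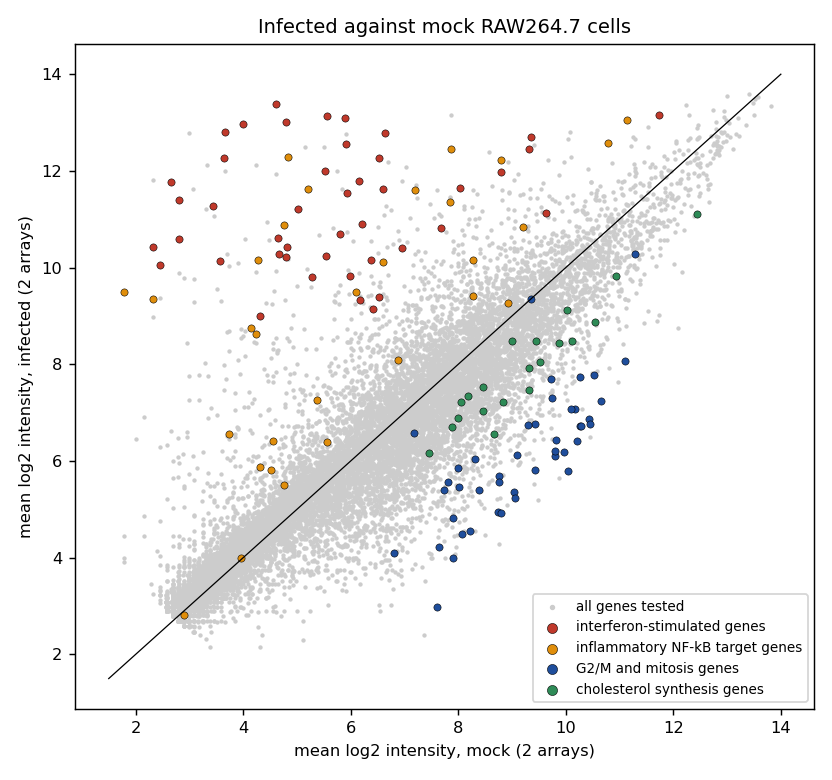
Mean log2 intensity of each tested gene in infected cells (y axis, 2 arrays) against mock cells (x axis, 2 arrays), with members of 4 gene lists in colour and a line of equal level. Interferon-stimulated genes lie above the line (median log2 change 5.62) and genes of G2/M and mitosis mostly below it (median -3.14).

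Interferon-stimulated genes rose as a group. All 44 measured members rose, with a median log2 change of 5.62 (49.2-fold) and a range from 1.43 for Ifitm3 to 9.14 for Ifit1. The count was also 44 adjusted over the list alone. Ifit1, which binds foreign RNA, read 6820 and 7497 in infected and 10 and 16 in mock arrays (SE 0.27), and its partner Ifit3 read 8115 and 7920 against 21 and 12 (SE 0.31). Mx1, a GTPase that blocks viruses, read 3305 and 3726 against 8 and 5 (SE 0.27). Ifnb1, which encodes the interferon that induces such genes, rose from 11 and 11 to 1989 and 2337 (log2 change 7.61, SE 0.12, adjusted p = 0.00137, limma). The list passed camera (adjusted p = 5.17e-29) and did not pass with an estimated correlation (adjusted p = 0.306). Several of these genes have close relatives, among them the Ifit, Oas and Gbp families, and a probe set may also read a relative.

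Of 30 inflammatory NF-kB target genes, 26 rose, also 26 adjusted over the list alone, with a median log2 change of 2.36. The cytokine gene Il6 and Ptgs2, the inducible prostaglandin synthase, were at the negative controls in mock cells and were at least 119.9-fold and 108-fold higher in infected cells. The chemokine gene Ccl5 rose by a log2 change of 7.45 (SE 0.24) and Tnf by 3.51 (SE 0.11). The 4 members that did not pass were Il12b (-0.10), Csf2 (0.05), Tnfaip2 (0.35) and Saa3 (0.85). Immediate early genes, which respond to signalling without new protein synthesis, had 13 of 19 members higher and none lower (13 adjusted over the list alone). Their leaders were the transcription factor genes Egr1 (5.79, SE 0.16) and Egr2 (3.68, SE 0.26) and the phosphatase gene Dusp1 (5.06, SE 0.11). All 12 MHC class I presentation genes rose, 12 adjusted over the list alone, by a median of 2.28. Among them were the MHC class I transactivator Nlrc5 (4.33, SE 0.14) and the peptide transporter genes Tap1 (3.83, SE 0.11) and Tap2 (3.09, SE 0.20). Probe sets for H2-K1 and H2-D1 can read other MHC class I genes. The lists passed camera at an adjusted p of 7.58e-15 for NF-kB targets, 3.97e-06 for immediate early genes and 3.07e-08 for MHC class I presentation. With an estimated correlation the adjusted p was 0.306, 0.306 and 0.365.

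Genes of cell division fell. Of 44 G2/M and mitosis genes, 42 fell, also 42 adjusted over the list alone, with a median log2 change of -3.14. The spindle gene Aspm, the cytokinesis gene Anln (-4.25, SE 0.24) and the kinetochore gene Cenpf (-3.91, SE 0.44) fell furthest, although the probe sets of Aspm ranged from -4.62 to -0.24 and those of Cenpf from -3.91 to 0.11. Birc5, which encodes survivin, fell from 1188 and 1168 to 111 and 66 (-3.78, SE 0.29, adjusted p = 0.00664, limma). Ccna2, the cyclin of S phase and G2, had a change of -3.40 (SE 0.20, adjusted p = 0.0048, limma). The 2 members that did not pass were Foxm1 (-0.61) and Tpx2 (0.01). Of 40 G1/S and DNA replication genes, 33 fell (38 adjusted over the list alone), with a median of -2.19. The nucleotide enzyme genes Tk1 (-4.22, SE 0.17), Dut (-3.89, SE 0.45) and Rrm2 (-3.34, SE 0.14) led them. Ccne1, the G1/S cyclin, had a change of -0.81 (SE 0.19) that did not pass (adjusted p = 0.0522), and it passed in several other settings. Pcna (-0.29) and Cdt1 (0.28) did not pass either. Both lists passed camera, G2/M at an adjusted p of 5.79e-20 and G1/S at 3.52e-14. With an estimated correlation the adjusted p was 0.365 for each.

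The 22 G1 cyclins, their kinases and CDK inhibitors moved both ways, with 8 higher and 5 lower (8 and 7 adjusted over the list alone). The list median was 0.03, and the list did not pass (adjusted p = 0.743). The median was -0.06 with each array centred on its median, -0.34 with a filter at the median intensity and -0.43 above an intensity of 64. Btg2, an antiproliferative gene, rose most (3.14, SE 0.10). Ccnd1, a G1 cyclin, rose by 0.61 (SE 0.078), the CDK inhibitor gene Cdkn1a by 1.02 (SE 0.11) and Myc, a growth-promoting transcription factor gene, by 2.06 (SE 0.16). The 5 members that fell were Cdk4 (-2.13), Rbl2 (-2.02), Cdkn2c (-1.79), Cdk2 (-1.43) and Rbl1 (-0.68), of which Rbl1, Rbl2 and Cdkn2c restrain the cell cycle. Of 22 p53 target genes, 8 rose and 4 fell, the same adjusted over the list alone (median 0.21, list adjusted p = 0.205). The median turned to -0.11 with a filter at the median intensity and to -0.029 without infected replicate 2, while above an intensity of 64 the list was called higher (0.38, adjusted p = 0.038). Plk2, a stress-induced kinase gene, rose by 3.98 (SE 0.16, another probe set at 0.94), and Sesn1 (-3.07), Zmat3 (-2.76), Ei24 (-0.84) and Tigar (-0.84) were the members that fell.

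**Figure D2:**
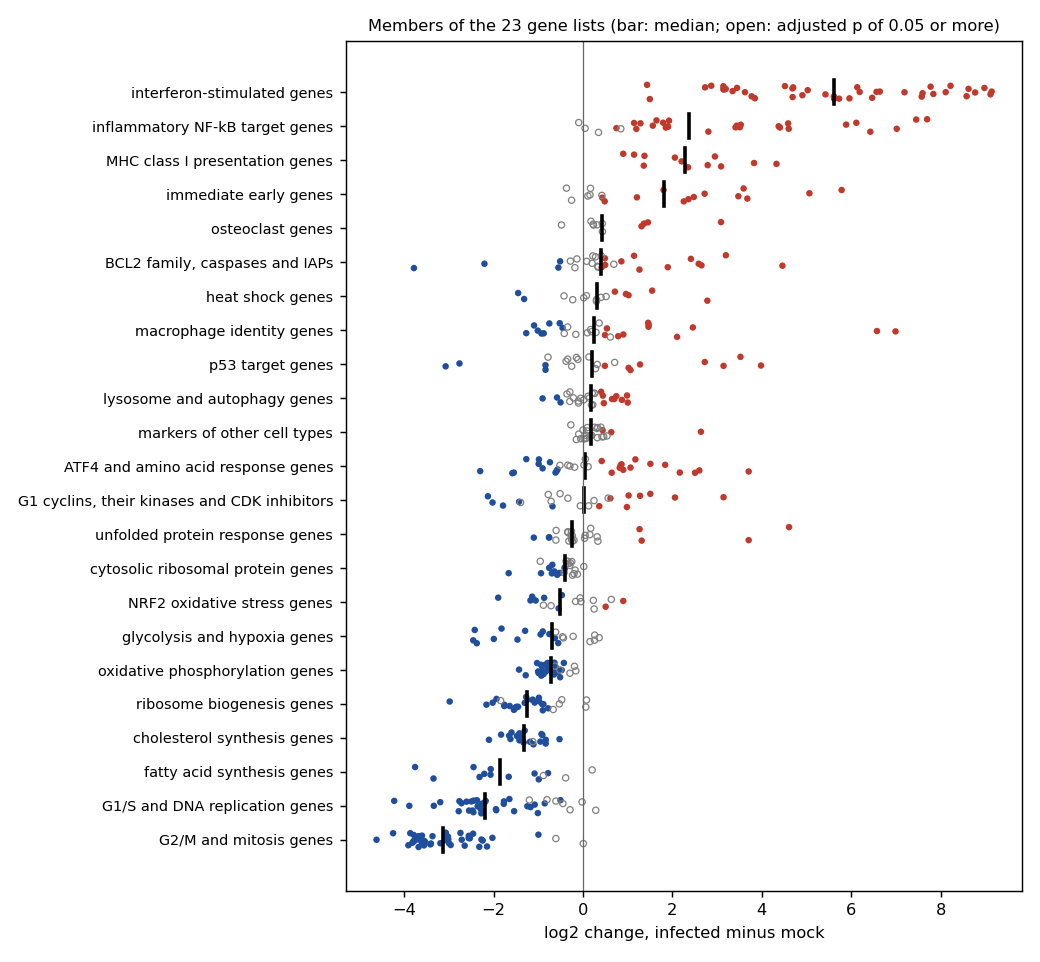
Log2 change of each tested member of the 23 gene lists (x axis, infected minus mock), with lists in rows ordered by their median, shown as a bar. Filled points have an adjusted p under 0.05 (red higher, blue lower) and open points do not. Medians run from -3.14 for G2/M and mitosis genes to 5.62 for interferon-stimulated genes.

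Among 27 genes of the BCL2 family, caspases and inhibitors of apoptosis, 12 rose and 4 fell, the same adjusted over the list alone (median 0.41). The list held genes that promote and genes that oppose cell death, and both kinds rose. Casp4, an inflammatory caspase, rose by 4.46 (SE 0.096), the pro-apoptotic Bmf by 3.20 (SE 0.27) and Cflar, which restrains caspase-8, by 2.65 (SE 0.15). Other probe sets of Bmf went down to -0.57 and those of Cflar to 0.21. The 4 members that fell were Birc5 (-3.78) and Bcl2 (-2.21), which oppose apoptosis, and Htra2 (-0.55) and Casp6 (-0.51), which promote it. The list passed camera (adjusted p = 0.00477) and did not pass with an estimated correlation (adjusted p = 0.365).

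Stress-response lists gave a mixed picture. Of 24 unfolded protein response genes, 4 rose and 3 fell, the same adjusted over the list alone, and the list did not pass (adjusted p = 0.601). Its median was -0.24 (0.01 under cyclic loess) and its mean 0.24. Ppp1r15a, a phosphatase subunit that reverses the translation block, rose by 4.61 (SE 0.17) and Ddit3, a stress transcription factor gene, by 3.71 (SE 0.18), with another probe set of Ddit3 at 0.53. Dnajb9 (1.31) and Syvn1 (1.26) rose too, while Sdf2l1 (-1.10), Sel1l (-0.76) and Canx (-0.76) fell and the chaperone gene Hspa5 did not pass (0.15). Of 32 ATF4 and amino acid response genes, 14 rose and 11 fell (14 and 12 adjusted over the list alone), with a median of 0.04 (-0.06 with each array centred on its median) and a list adjusted p of 0.497. The largest mover was Ddit3. Atf3 (2.60) rose and Shmt2 (-2.30) and Psat1 (-1.55) fell, while Cebpg (-0.29) and Mthfd2 (-0.52) did not pass. Of 15 heat shock genes, 5 rose and 2 fell (7 and 2 adjusted over the list alone). The median was 0.30 and the list did not pass (adjusted p = 0.12), but it passed without mock replicate 1 (adjusted p = 0.0344). Hspa1b, an inducible chaperone gene nearly identical to Hspa1a, rose by 2.78 (SE 0.17), and Fkbp4 (-1.45) and Hspd1 (-1.32) fell. Of 18 NRF2 oxidative stress genes, 8 fell and 2 rose (10 and 2 adjusted over the list alone), with a median of -0.51. The leading falls were Gclc, for glutathione synthesis (-1.90, SE 0.17), the catalase gene Cat (-1.18, SE 0.15) and Taldo1 (-1.14, SE 0.13), while Slc7a11 (0.90) and Txn1 (0.51) rose. This list passed narrowly (adjusted p = 0.0421). It did not pass with an estimated correlation (adjusted p = 0.581), without infected replicate 1 (0.0854), infected replicate 2 (0.062) or mock replicate 2 (0.122), under 3 rescalings of the arrays, or with a filter at the median intensity (0.17) or fry (0.0548).

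Lipid synthesis genes fell. Of 20 cholesterol synthesis genes, 19 fell, also 19 adjusted over the list alone (median -1.32). Mvd (-2.10, SE 0.10), Cyp51 (-1.83, SE 0.25) and Hmgcs1 (-1.65, SE 0.32), enzymes of the pathway, fell furthest, and Hmgcs1 did not pass when no filter on dim genes was used (adjusted p = 0.0658). Of 14 fatty acid synthesis genes, 11 fell (13 adjusted over the list alone) with a median of -1.86. The elongase gene Elovl6 fell from 225 and 208 to 16 and 16 (-3.76, SE 0.089), and the desaturase genes Scd2 (-3.35, SE 0.20) and Scd1 (-2.45, SE 0.17) followed. Of 20 glycolysis and hypoxia genes, 12 fell (13 adjusted over the list alone) and none rose (median -0.69). Pdk1, a pyruvate dehydrogenase kinase gene (-2.46, SE 0.40), and the hypoxia-induced Ankrd37 (-2.42, SE 0.21) and Adm (-2.38, SE 0.14) led. Of 34 oxidative phosphorylation genes, 29 fell (31 adjusted over the list alone) with a median of -0.72, led by the respiratory chain genes Uqcrb (-1.43, SE 0.17), Sdhd (-1.28, SE 0.17) and Cyc1 (-1.03, SE 0.12). In camera the adjusted p was 1.88e-08 for cholesterol synthesis, 2.17e-06 for fatty acid synthesis, 0.000419 for glycolysis and hypoxia and 5.02e-10 for oxidative phosphorylation. With an estimated correlation the adjusted p was 0.372, 0.365, 0.365 and 0.372.

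Genes for making ribosomes fell too. Of 30 ribosome biogenesis genes, 24 fell (28 adjusted over the list alone) with a median of -1.26, led by Dkc1 (-2.98, SE 0.34), Nolc1 (-2.16, SE 0.096) and Rrp12 (-2.02, SE 0.26), which act in the nucleolus. Of 24 cytosolic ribosomal protein genes, 11 fell (18 adjusted over the list alone) with a smaller median of -0.41, which became -0.12 under cyclic loess, where the list no longer passed (adjusted p = 0.103). Rpl14 (-1.66, SE 0.28), Rpl8 (-0.94, SE 0.085) and Rps9 (-0.76, SE 0.12) fell furthest among those that passed, and Rpl14 did not pass without a filter (adjusted p = 0.0511). The Rpl14 probe set was dim, at 49 and 32 in infected and 143 and 110 in mock arrays. Rpl8 read 3423 and 3239 against 6298 and 6473. Ribosomal protein genes have many near-identical pseudogenes, and their probe sets may read those. In camera the adjusted p was 9.16e-10 for ribosome biogenesis and 3.97e-06 for ribosomal proteins. With an estimated correlation the adjusted p was 0.365 and 0.376.

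Macrophage identity genes moved in both directions. Of 28 members 11 rose and 8 fell (13 and 10 adjusted over the list alone), with a median of 0.24 and a list adjusted p of 0.152. The Fc receptor gene Fcgr1 rose from 44 and 47 to 5583 and 5997 (6.99, SE 0.094). Cd300lf, the gene of the receptor through which murine norovirus enters cells, rose from 73 and 56 to 177 and 177 (1.47, SE 0.16, adjusted p = 0.0117, limma). The macrophage surface genes Itgam (-1.27), Adgre1 (-1.09) and Csf1r (-1.01) fell. Of 11 osteoclast genes, 4 rose and none fell, the same adjusted over the list alone (median 0.43, camera adjusted p = 0.00863, adjusted p = 0.365 with an estimated correlation). They were Atp6v0d2 (3.09, SE 0.30), Acp5 (1.45, SE 0.086), Ocstamp (1.36, SE 0.10) and Dcstamp (1.31), of which Ocstamp and Dcstamp act in cell fusion. Of 27 lysosome and autophagy genes, 9 rose and 3 fell (9 and 4 adjusted over the list alone), with a median of 0.19 and a list adjusted p of 0.127. The lysosomal enzyme gene Gla rose by 1.00 (SE 0.079) and Hexa (-0.90), Ctsa (-0.58) and Mcoln1 (-0.50) fell. Of 24 markers of other cell types, 3 rose and none fell (1 and 0 adjusted over the list alone). Kdr, an endothelial receptor gene, rose from 20 and 20 to 136 and 114 (2.64, SE 0.12), while Mpo (18 and 16 against 10 and 12) and Hba-a1 (9 and 10 against 7 and 7) were dim in both groups. The list did not pass (adjusted p = 0.0559), but it passed without infected replicate 1 (adjusted p = 0.025).

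**Figure D3:**
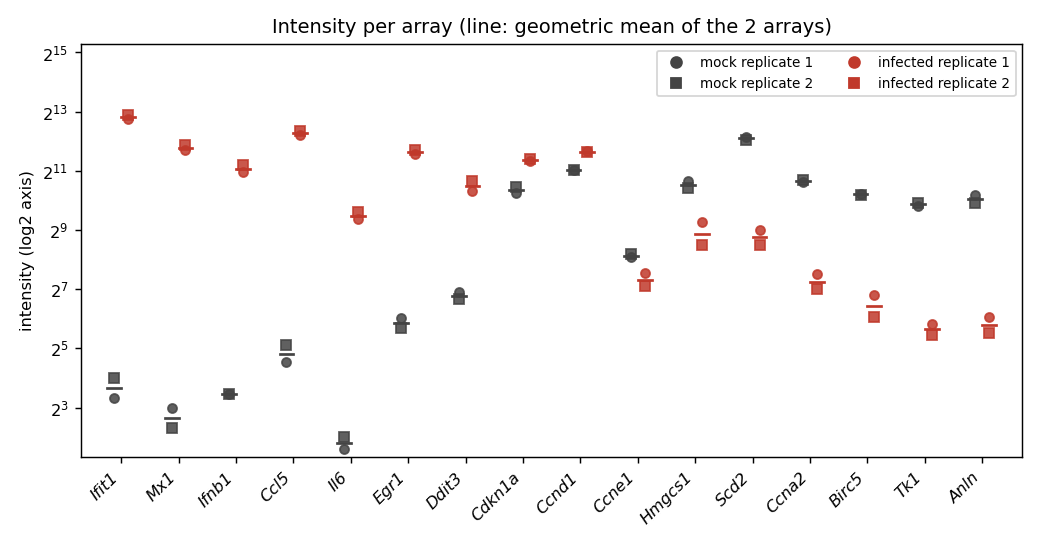
Intensity of 16 genes on each of the 4 arrays (y axis, log2 scale), mock in grey and infected in red, with circles for replicate 1, squares for replicate 2 and a line at the geometric mean. Both infected arrays lie above both mock arrays from Ifit1 to Ccnd1 and below them from Ccne1 to Anln.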

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

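The tests of the B2 repeat and 18S signals below were chosen only after those signals were seen. All these values come from probe sets that the comparison of named genes did not use.

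Among the 6107 probe sets above the intensity filter that had no gene or several genes in the annotation used, 378 were higher and 375 lower in infected cells, with the same limma test and threshold. A rise of at least 4-fold was seen in 77 of them, and the largest log2 rise was 9.19.

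The array's control probe set for the mouse B2 repeat, a short interspersed element transcribed by RNA polymerase III, read 922 and 1205 in infected and 436 and 375 in mock arrays, a log2 change of 1.382. If scaling of the arrays or a rise of all repeat RNA lay behind it, the control for the B1 repeat should rise alike, but that control changed by 0.119. The weak labelling controls of mock replicate 2 do not account for it either, since the change was 1.274 without that array. A second B2 control changed by 0.43 near the top of the intensity range (16144 and 16184 against 12576 and 11390), where a larger change might not show. A rise of B2 transcripts with infection stays a hypothesis, as do longer host transcripts that contain the repeat, which these probe sets do not separate.

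The 5' control for 18S ribosomal RNA read 550 and 388 in infected and 63 and 16 in mock arrays, a log2 change of 3.863. General breakage of RNA in the infected samples would raise the 3' minus 5' difference of the beta-actin and Gapdh controls in both infected arrays. For beta-actin, infected minus mock, it was -0.2174, and it was lower in both infected arrays than in either mock array. For Gapdh it was 0.04687, with infected replicate 2 (-0.02165) above and infected replicate 1 (-0.1537) below both mock arrays (-0.1423 and -0.1268). These controls read messenger RNA, so breaks limited to ribosomal RNA were not tested and stay open. More ribosomal RNA in the labelled samples would raise all 18S controls alike, but the middle control changed by 1.204 and the 3' control by 0.3865. These sizes lean on mock replicate 2, the array with weak spikes: without it the changes were 2.874 for the 5' control, 0.4115 for the middle one and -0.4333 for the 3' one, still unequal. A difference in labelling between the groups cannot be separated from infection with these arrays.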

How the results depend on the processing

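The intensity filter of 64, alone or with an array left out, and the rounding draws were chosen only after seeing the data. Rescaling left 1927 genes higher and 3797 lower with median centring, 2778 and 3075 with quantile normalisation, and 3082 and 3094 with cyclic loess. With every probe set as its own feature 4891 were lower, where more features were tested, and with a 2-fold limit, stricter by construction, 1082 were higher and 1679 lower. With any 1 array left out limma's counts were 0 to 0 in both directions, with 4879 to 6080 genes at an unadjusted p under 0.05. Then 1 residual degree of freedom remained, the lone array of a group was assumed to vary like the other group, 7.96% to 9.48% of genes had no spread, and the prior fell to 0.696 to 0.768 degrees of freedom. Above an intensity of 64, 1213 genes were higher without infected replicate 1, 1258 were higher without infected replicate 2 and 1935 were lower without mock replicate 1, with fewer genes and arrays in the test. The replicate numbers are not known to pair the arrays: deviations of same-numbered arrays correlated at 0.2551 over genes, with 2 pairs only. With the replicate number as a block, 1726 genes were higher and 2475 lower, 3842 of the 5048 calls were shared, and the calls of Cat, Sdhd, Rps9 and the NRF2 list ended, while that of the other cell types was gained. The NRF2 call also ended with the filter at the median (adjusted p = 0.17), with fry (0.0548), above 64 (0.179) and with the rounding draws (0.0559). With an estimated correlation camera called 0 lists higher and 0 lower (3 at an unadjusted p under 0.05), while fry, which does not compare a list with other genes, called 11 higher. The lists whose median changed sign were not called in the settings that changed it, and, median centring aside, the cause was not tested. Median centring moved all genes of an array alike, by whole-number array medians. With it the median over the genes tested went from 0.027 to -0.069. The median of the G1 cyclins list became -0.061 without a filter, -0.34 with the filter at the median, -0.064 with median centring and -0.43 above an intensity of 64. It was -0.61, -0.31, -0.41 and -0.33 above that intensity without infected replicate 1, infected replicate 2, mock replicate 1 and mock replicate 2, and -0.029 to 0.057 with single arrays left out. That of the p53 list became -0.11 with the filter at the median and ranged from -0.029 to 0.35 with single arrays left out, while above an intensity of 64 this list was called higher (0.38, adjusted p = 0.038), also there without mock replicate 1 (0.55) or mock replicate 2 (0.42). The macrophage list was called higher above 64 as well (0.33, adjusted p = 0.038), and there without infected replicate 1 (0.37), as was the lysosome list without infected replicate 1 (0.18) or mock replicate 2 (0.22). That of the ATF4 list became -0.060 with median centring and -0.019 above 64 without infected replicate 1, and ranged from -0.073 to 0.085. That of the unfolded protein list became 0.014 under cyclic loess, which also called the heat shock, lysosome and macrophage lists higher. Dim signal also limits these data, as 51 called genes were at the negative controls in mock and 12 in infected cells.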

Other observations

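The 6 gene groups of the next paragraph and their members were chosen only after seeing the data, and so are not independent of it. Some groups also share members with lists called above. Ifih1, Ddx58, Dhx58, Zbp1 and Irf7 of the sensor group are in the interferon list. Among the feedback inhibitors, Usp18 is in the interferon list, and Dusp1 and Zfp36 are in the immediate early list. Socs3, Tnfaip3, Nfkbia, Zc3h12a and Il1rn of that group are in the NF-kB list. Of the pyroptosis and necroptosis genes, Casp1 and Casp4 are in the BCL2 list and Il1b is in the NF-kB list. Zbp1 of that group is in the interferon list and in the sensor group. Such groups are not separate evidence from those lists. The tests of the difference between the infected arrays were written before their results were seen.

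Enzymes of purine and pyrimidine synthesis fell, 15 of 16 measured members, also 15 adjusted over the list alone, among them Cad (-2.97, another probe set at -0.86), Pfas (-2.92) and Ctps (-2.61). The group's median log2 change was -2.12 (camera adjusted p = 8.13e-08 over these 6 groups, adjusted p = 0.293 with an estimated correlation). Of 21 condensin and cohesin genes 14 fell (2 higher and 15 lower adjusted over the list alone), with a median of -1.42 (adjusted p = 2.49e-05, and 0.35 with an estimated correlation). The condensin genes Ncapd2 (-3.86, another probe set at -0.44) and Ncapg2 (-3.52) fell, as did the cohesin ring genes Smc3 (-1.72, another probe set at -0.52), Rad21 (-1.24) and Smc1a (-1.17), and the cohesin subunit genes Stag1 (-0.85) and Stag2 (-0.45) did not pass. The complexes were not tested against each other. Of 40 mitochondrial ribosomal protein genes 23 fell and 1, Mrpl13 (0.87), rose (26 and 2 adjusted over the list alone), with a median of -0.80 (adjusted p = 3.29e-07, and 0.35 with an estimated correlation). Sensors of nucleic acids and their adaptors rose in 13 of 17 cases (14 higher and 2 lower adjusted over the list alone), with a median of 1.68 (adjusted p = 3.29e-07, and 0.158 with an estimated correlation). Tlr3 (6.58) and Ifih1 (5.61), which detect viral RNA, rose. Mavs (-0.34), which acts downstream of Ifih1, and Irf3 (-0.35), downstream of both, did not pass over all genes. They were the 2 that passed as lower over the list alone. Genes of pyroptosis and necroptosis had 9 of 13 members higher and 1 lower (10 and 1 adjusted over the list alone), with a median of 1.70 (adjusted p = 2.57e-05, and 0.158, or 0.0469 unadjusted, with an estimated correlation). The pore former Gsdmd (2.09) and the necroptosis effector Mlkl (3.49) rose, and the pore former Gsdme fell (-3.32, another probe set at -0.78). Feedback inhibitors of inflammatory signalling had 16 of 19 members higher and 1, Irak3 (-0.71), lower, the same adjusted over the list alone. Cd274 (5.32) and Il10 (4.10) rose among them, and the group's median was 2.86 (adjusted p = 3.27e-09, and 0.158 with an estimated correlation).

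Among genes lower in infected cells, infected replicate 2 lay below infected replicate 1 in 80.27% of 2914 genes, by a median of -0.1895 log2 units. Uncalled genes of matched intensity had a median of -0.074, so an intensity-dependent difference between these arrays leaves -0.1155 without an account. Compression of dim signals is not excluded: among the 1236 brighter of the lower genes the excess over matched genes was -0.05732, and it did not pass the range of matched sets by the margin set in advance. Genes higher in infected cells had a median of -0.01238 between the same arrays, with 52.39% of 2132 below 0, so they did not themselves lie further from mock in infected replicate 2. They lay 0.07102 above matched uncalled genes, whose median was -0.08341. A stronger response in infected replicate 2 therefore stays open, and a single pair of arrays cannot settle it.

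The hybridization spikes had geometric means of 963.7 and 1021 in infected replicates 1 and 2, 809.3 in mock replicate 1 and 546.9 in mock replicate 2, over 9 probe sets. The poly-A spikes of the other 3 arrays were 2.43 to 3.32 times as bright as those of mock replicate 2.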
